A study of Homo sapiens with 6 samples.

How the data were processed

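Gene expression was measured by RNA-seq in 6 libraries of A549 cells, 3 untreated controls and 3 exposed to polystyrene microplastics (PS-MPs, 20 mg/mL, 48 h, as the labels give the dose). Per the labels' protocols, cells grew in DMEM with fetal bovine serum, RNA was extracted with TRIzol, libraries were made with an Illumina stranded mRNA kit after poly(A) selection, and paired-end reads were sequenced on a NovaSeq X Plus. The values used were whole-number counts per Ensembl gene, as deposited, 1 column per library and 62710 genes. Per the submitters' processing notes, the tools were fastp, HISAT2, StringTie, RSEM and DESeq2 with the genome build GRCh38, with no version or role for any of them, and the deposited counts carry the name of featureCounts. The strand setting, the handling of reads that map to several places and the annotation release are not stated in the sources used here, so overlapping genes and near-identical gene families are reported as uncertain. Of the gene IDs, 92.9% were found in GENCODE release 29, and 99.97% of those overlapped their position there.

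The design, the gene lists, the rule for named genes and all alternatives except the one that leaves out both replicate 3 libraries were chosen before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr on the group (15458 genes, while 29707 had 0 counts in all libraries), libraries were scaled by TMM, and PS-MP was compared with control by the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the tested genes at 0.05. The adjusted p of a gene in the text comes from this edgeR test unless another tool is named. CPM are TMM-normalised, means are given with the SD of 3 libraries, and the standard error of a log2 fold change is the approximate value obtained from the fold change and its F statistic. The common biological coefficient of variation was 0.138. Totals of 17013293 to 21316451 counts per library place 3 counts at 0.141 to 0.176 CPM, and such floors cover counting error only.

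The 30 gene lists cover ferroptosis suppressors and drivers, NF-kB target genes and pathway components, NRF2 targets, double-strand break repair, p53 targets, S phase, G2/M, cholesterol and fatty acid synthesis, the ATF4 response, endoplasmic reticulum chaperones, hypoxia, mesenchymal and epithelial genes, lysosome and autophagy, particle uptake, interferon-stimulated genes, heat shock, metal response, aryl hydrocarbon receptor targets, immediate early genes, oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins, alveolar type 2, leukocyte, fibroblast and endothelial markers, and non-polyadenylated RNAs. Lists were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 30 lists. Camera with an estimated correlation was run beside it, and so was fry, which tests whether the genes of a list move one way on balance and does not compare the list with other genes. Ranges of a list's adjusted p over its alternatives include fry. The score of a list in a library is the median over its tested members of log2 CPM minus the control mean. Named genes are the 8 with the largest rise and the 8 with the largest fall among called genes with a symbol, a mean log2 CPM of at least 2 and groups that do not overlap, the 2 called members of each list with the smallest adjusted p, and 10 ferroptosis and NF-kB genes given whatever their result. Other genes are named as examples chosen after their values were seen. Some genes that this rule selects are not reported here.

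Alternatives were DESeq2 1.42.0, RLE, upper-quartile and total-count scaling, no filter, a mean of at least 10 counts, limma-voom, the replicate number as a block, each library left out in turn, an absolute log2 fold change of at least 1, and protein-coding genes alone. The procedure was tested on simulated counts for the same 15458 genes with 200 of them changed by known folds. In the first draw edgeR recovered 30.3% of 33 genes changed 1.5-fold, 64.2% of 67 changed 2-fold and 95.5% of 66 changed 4-fold. Recovery was not counted for the rest of the 200. Over 10 further draws 7.9% of its calls were false (5.52% to 11.7%), above the nominal 5%. Camera called the list that had been shifted, and of the 29 lists that had not been it called 0. The simulated genes varied independently, so this test could not show false calls of lists whose genes vary together.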

Results

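The data were gene counts from poly(A)-selected, stranded RNA-seq libraries of A549 cells, an established human lung adenocarcinoma line that carries a mutated KEAP1. The libraries fell into 2 groups of 3. In the PS-MP group, polystyrene microplastics had been added to the culture at a labelled concentration of 20 mg/mL for 48 h, and the control group received none. That concentration is very high for a cell culture, and its unit could not be checked in the sources used here. The labels name no irradiation for any of the 6 libraries, so radiation responses were not analysed here. Total counts were 17013293, 21316451 and 20996260 in the controls and 17541896, 18628382 and 19119508 in the PS-MP libraries, where 3 counts correspond to 0.141 to 0.176 CPM (counts scaled to a library of 1e6). Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The counts of control replicates 1 and 2, the closest pair, differed by more than sampling noise (chi-square per degree of freedom 4.19), and each library was used as its own replicate.

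Groups separated on the first principal component of log2 CPM, which held 52.4% of the variance. Replicate 3 stood apart from replicates 1 and 2 in both groups. The correlation of control replicate 3 with its group was 0.984 and 0.985, against 0.994 between control replicates 1 and 2. PS-MP replicate 3 correlated at 0.984 and 0.981 with its group, against 0.992 between PS-MP replicates 1 and 2. Mitochondrially encoded transcripts took 12.4% of the counts in control replicate 3 and between 15.6% and 17.8% in the other 5 libraries.

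The comparison of PS-MP with control cells asks how exposure to the particles changes gene expression, with ferroptosis (iron-dependent death by lipid peroxidation), NF-kB signalling and radiotherapy resistance named in the series title. In the PS-MP libraries, genes of DNA replication and mitosis were lower, and p53 target genes, NF-kB target genes and many interferon-stimulated and lysosomal genes were higher. With an estimated correlation between genes, the p53 and NF-kB target lists kept their calls and the other 4 lists did not (adjusted p from 0.0631 to 0.11). MKI67, the proliferation marker, was 7.84-fold lower (142.9 ± 40.5 against 18.3 ± 6.16 CPM, mean ± SD, n = 3 per group). CDKN1A, which encodes the cell-cycle inhibitor p21, was 4.32-fold higher (124 ± 9.07 against 534 ± 110 CPM, n = 3). The cytokine transcript IL6 was 8.67-fold higher at a low level (0.562 ± 0.0229 against 4.92 ± 0.474 CPM, n = 3). GPX4, the central ferroptosis-suppressing lipid peroxidase, stood at 152.8 ± 8.78 CPM in the controls and 151.6 ± 16.0 CPM in the PS-MP libraries (n = 3). In the deposited annotation (GRCh38), MKI67 (ENSG00000148773) lies on chromosome 10 at 128096659 to 128126423, and CDKN1A (ENSG00000124762) on chromosome 6 at 36676460 to 36687337. IL6 (ENSG00000136244) lies on chromosome 7 at 22725884 to 22732002 and GPX4 (ENSG00000167468) on chromosome 19 at 1103982 to 1106791.

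By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 1478 of 15458 tested genes differed, 759 of them higher and 719 lower in PS-MP cells. That is 9.56% of the tested genes, the share to set beside the called members of each list. The shares called among ferroptosis drivers and NRF2, ATF4, cholesterol, mesenchymal, chaperone, oxidative phosphorylation and uptake genes lay near or below it. With total counts as the only scaling, 535 genes were higher and 861 lower. At least 2-fold changes were more often falls (345 genes) than rises (213 genes). The groups did not overlap in 32% of the tested genes, where chance gives 10% on average for 3 against 3. Because genes vary together, 1 split can lie far from that average, so these shares are no test. The count of called genes depended on the libraries. It was 887 without control replicate 1, 896 without control replicate 2, 771 without PS-MP replicate 1 and 799 without PS-MP replicate 2. Leaving out both replicate 3 libraries, a choice made after the data were seen, gave 4129 of 15503 tested genes, among them 1452 of the 1478. That setting removes the libraries farthest from the rest of their groups, so more genes pass in general. Counts of list members under it are to be read against that number, and their increase is no separate evidence.

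**Figure D1:**
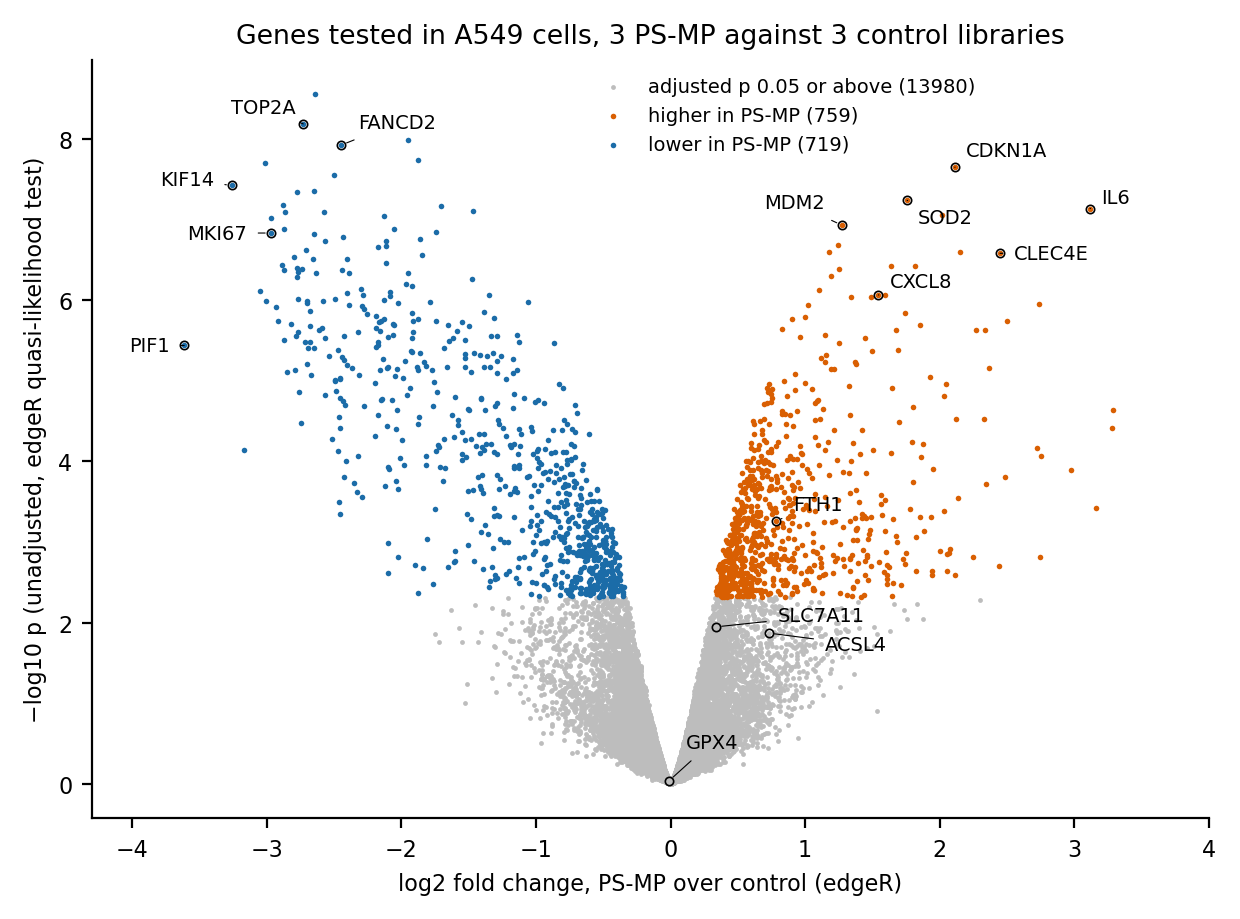
Each point is 1 of the 15458 tested genes, with its log2 fold change (PS-MP over control) on the x axis and the −log10 of the unadjusted edgeR p on the y axis; orange and blue mark the 759 higher and 719 lower genes at an adjusted p under 0.05, and circles mark named genes. TOP2A, FANCD2 and MKI67 lie at the upper left, CDKN1A, SOD2 and IL6 at the upper right, and GPX4 (log2 fold change −0.01) at the bottom centre.

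Of the 30 lists, the G2/M and mitosis list had the lowest median. All 25 tested members of the G2/M and mitosis list fell, over all genes tested and adjusted over the list alone, with a median log2 fold change of −2.70. TOP2A, the DNA topoisomerase of dividing cells, was 6.63-fold lower (281 ± 30.1 against 42.4 ± 10.4 CPM, n = 3, adjusted p = 4.61e-05), and CENPF, a kinetochore protein, was 6.83-fold lower (46.0 ± 11.4 against 6.749 ± 1.499 CPM, adjusted p = 6.4e-05). In the list of S-phase and replication genes 25 of 26 tested members fell, also when adjusted over the list alone (median −1.62). The replication licensing factor CDT1 was 4.07-fold lower and the replicative helicase subunit MCM2 4.37-fold lower, while CCNE1 (log2 fold change −0.17, adjusted p = 0.478) did not pass. The 8 steepest falls among called genes with a mean log2 CPM of at least 2 and groups that do not overlap were those of PIF1, KIF14, KIF20A, DIAPH3, TTK, MKI67, KNL1 and DLGAP5. They were between 7.63-fold and 12.2-fold lower. The 12.2-fold fall was that of PIF1 (8.26 ± 2.85 against 0.681 ± 0.473 CPM, n = 3). In PS-MP replicate 3 it had 0.212 CPM, near the 0.157 CPM of 3 counts there. Its log2 fold change ran from −4.22 to −2.85 over the alternatives. Most of the 8 genes act in chromosome segregation or cytokinesis, for example the mitotic kinesins KIF14 and KIF20A and the spindle checkpoint kinase TTK. Camera gave both lists an adjusted p far under the threshold (1.38e-90 for G2/M, 1.16e-44 for S phase). With an estimated correlation the calls were lost (adjusted p = 0.0631 for G2/M and adjusted p = 0.11 for S phase), the highest values of 17 alternatives, which reached down to 6.39e-136 and 2.56e-66. The replicate 3 libraries differed from the others along these genes. The median of the 51 tested members of both lists lay 0.66 above replicates 1 and 2 in control replicate 3 and −0.73 from them in PS-MP replicate 3, on the log2 scale. Once both were left out, 25 G2/M genes (median −2.19) and 25 S-phase genes (median −1.33) still passed as lower.

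The p53 target list moved the other way. Of its 28 tested members 25 rose over all genes tested, and all 28 rose when adjusted over the list alone (median 0.95). Beside CDKN1A (log2 fold change 2.11 ± 0.15 SE, adjusted p = 4.97e-05), the ubiquitin ligase MDM2 rose 2.42-fold (67.2 ± 3.73 against 162.4 ± 14.0 CPM, n = 3, adjusted p = 8.26e-05) and the stress sensor SESN2 2.28-fold. AEN, DDB2 and TP53I11 (log2 fold changes 0.42, 0.27 and 0.33) passed only within the list. The list was called by camera (adjusted p = 2.3e-42) and with an estimated correlation (adjusted p = 0.00295), the extremes over its alternatives being 6.84e-70 and 0.00295. The 25 risers became 21 without control replicate 1 or with the replicate number as a block, and 26 without control replicate 3. When both replicate 3 libraries were left out, 27 members were higher.

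DNA double-strand break repair genes, which bear on the radiotherapy question of the series, were lower as a list. Over all genes tested 14 of the 32 members fell and none rose, and 22 fell when adjusted over the list alone (median −0.53). The members with the smallest adjusted p were FANCD2, of the Fanconi anaemia pathway, and BRCA1, of homologous recombination. FANCD2 was 5.44-fold lower (33.8 ± 3.41 against 6.22 ± 1.16 CPM, n = 3, adjusted p = 4.61e-05) and BRCA1 3.59-fold lower (30.2 ± 5.34 against 8.41 ± 1.18 CPM, adjusted p = 0.000109). Among end-joining factors, XRCC4, XRCC5, XRCC6 and PRKDC (log2 fold changes −0.55, −0.29, −0.34 and −0.45) passed only within the list, with adjusted p from 0.0506 to 0.123 over all genes, and LIG4 (0.10) and NHEJ1 (−0.01) passed neither way. Transcripts of the damage kinase ATM (−0.06, adjusted p = 0.892) and of TP53BP1 (−0.06, adjusted p = 0.784) did not pass either. The call held with camera (adjusted p = 5.58e-23) and with an estimated correlation (adjusted p = 0.0423), the highest value of 17 alternatives that reached down to 4.23e-40. Many homologous recombination genes are known to be transcribed mainly in S phase and G2, the phases whose genes fell, and no test separated the repair list from them. In control replicate 3 this list scored 0.15 above the control mean and in PS-MP replicate 3 −0.48 from it, against −0.61 and −0.63 in PS-MP replicates 1 and 2. The 14 falls became 11 without PS-MP replicate 1, 12 without control replicate 1, 13 with the replicate number as a block and 18 by DESeq2. With both replicate 3 libraries left out, 24 members were lower.

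NF-kB target genes rose broadly. Of the 39 tested members 25 were higher over all genes tested and 28 when adjusted over the list alone, none was lower, and the median log2 fold change was 0.78. SOD2, the mitochondrial superoxide dismutase, rose 3.38-fold (197 ± 26.9 against 667 ± 83.4 CPM, n = 3, adjusted p = 7.01e-05) and the neutrophil chemokine CXCL8 2.92-fold (119 ± 17.0 against 346 ± 64.1 CPM, adjusted p = 0.000195). The chemokine genes CXCL1, CXCL2, CXCL3 and CCL20 were higher as well (log2 fold changes 1.24, 1.13, 1.45 and 1.85, examples chosen after their values were seen). TNFAIP3, which encodes the inhibitor A20, rose as well (log2 fold change 1.18, adjusted p = 0.000107). NFKBIA, which encodes the inhibitor IkB-alpha, stood at 122 ± 30.0 CPM in the controls and 126 ± 21.7 CPM in the PS-MP libraries (log2 fold change 0.05 ± 0.18 SE, adjusted p = 0.904). Its direction turned with total counts as the only scaling (log2 fold change −0.02) and without control replicate 3 (−0.15), PS-MP replicate 2 (−0.06) or both replicate 3 libraries (−0.01), with adjusted p from 0.57 to 0.983 over the alternatives. BIRC3 and NFKB2 (log2 fold changes 0.12 and 0.15) are further examples, chosen after their values were seen, of the 14 members that did not pass over all genes. Camera called the list (adjusted p = 3.04e-31), and so did the test with an estimated correlation (adjusted p = 0.0423), the highest value of 17 alternatives that reached down to 5.07e-50. The 25 risers became 18 without control replicate 1, 19 without control replicate 2 or PS-MP replicate 1, and 20 with the replicate number as a block. After both replicate 3 libraries were left out, 29 members were higher and 1 lower.

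The 20 tested NF-kB pathway components held 3 genes that rose, both over all genes tested and adjusted over the list alone. These were the Toll-like and interleukin-1 receptor signalling genes IRAK1 (1.49-fold, adjusted p = 0.0124), MYD88 (1.36-fold, adjusted p = 0.033) and TLR4 (log2 fold change 0.81, adjusted p = 0.0477). The subunit genes RELA (53.9 ± 2.64 against 57.9 ± 5.34 CPM, n = 3, adjusted p = 0.6) and NFKB1 (29.6 ± 1.34 against 33.0 ± 3.84 CPM, adjusted p = 0.462) did not pass, nor did the component list (median 0.02, camera adjusted p = 0.28, and adjusted p = 0.452 with an estimated correlation). IRAK1 lost its call without control replicate 2, PS-MP replicate 1 or PS-MP replicate 2 (adjusted p = 0.052, 0.0731 and 0.0616), and MYD88 lost it without any 1 of these or control replicate 1 (adjusted p from 0.0904 to 0.169) and with total counts as the only scaling (0.0784). That scaling left 1 riser in the component list, and limma-voom left 2. The replicate number as a block left 0, with an adjusted p of 0.0505 for IRAK1 and 0.118 for MYD88. TLR4, named after its value was seen, lost its call without control replicate 1 or 3 or PS-MP replicate 1 or 3 (adjusted p from 0.104 to 0.155).

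Among the 28 tested ferroptosis suppressors 5 rose and 1 fell over all genes tested, and 9 rose and 1 fell when adjusted over the list alone (median 0.18). FTH1, the ferritin heavy chain that stores iron, rose 1.72-fold (1210 ± 78.0 against 2082 ± 491 CPM, n = 3, adjusted p = 0.0119). AIFM2, which encodes the coenzyme Q reductase FSP1, rose 1.42-fold (39.6 ± 1.52 against 56.1 ± 7.01 CPM, n = 3, adjusted p = 0.0208). The other risers were GCH1, SQSTM1 and HSPB1 (log2 fold changes 0.45, 0.88 and 0.36, named after their values were seen), and the member that fell was FANCD2, which is also on the repair list. SLC7A11, the cystine transporter subunit, had 235.2 ± 4.88 CPM in the controls and 297.8 ± 39.2 CPM in the PS-MP libraries (1.27-fold). It did not pass over all genes (adjusted p = 0.087, and 0.0301 to 0.316 over its alternatives) and passed within the list (0.0315). GPX4 had a log2 fold change of −0.01 ± 0.11 SE (adjusted p = 0.964). It turned to 0.02 without control replicate 3, 0.004 without PS-MP replicate 1, 0.06 without PS-MP replicate 3 and 0.08 without both replicate 3 libraries. FTH1 and AIFM2 lost their calls without control replicate 2, PS-MP replicate 1 or PS-MP replicate 2 (adjusted p from 0.0504 to 0.0972), FTH1 also without control replicate 3 (0.0501) and AIFM2 also without control replicate 1 (0.072). GCH1, SQSTM1 and HSPB1 lost theirs without any 1 of the controls or PS-MP replicate 1 or 2 (adjusted p from 0.054 to 0.202), and HSPB1 also without PS-MP replicate 3 (0.0646). As a list the suppressors were not called (camera adjusted p = 0.119, and adjusted p = 0.503 with an estimated correlation). Their score was 0.22 and 0.25 above the control mean in PS-MP replicates 1 and 2 and 0.02 in PS-MP replicate 3, and without that library the adjusted p was 0.00151, against 0.000179 to 0.503 over all alternatives. Leaving out both replicate 3 libraries, 14 members were higher and 1 lower.

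No ferroptosis driver fell, and the median of the list was 0.15. By both adjustments 3 of the 27 tested drivers rose, near the share of 9.56% called over all tested genes. These were the fatty acid desaturase FADS1 (1.60-fold, 392 ± 25.9 against 627 ± 41.5 CPM, n = 3, adjusted p = 0.00201), the oxidoreductase CYB5R1 (1.496-fold, adjusted p = 0.00553) and the haem oxygenase HMOX1 (1.70-fold, adjusted p = 0.016). ACSL4, which loads membranes with oxidisable fatty acids, had 123.5 ± 3.46 CPM in the controls and 205.1 ± 97.2 CPM in the PS-MP libraries and did not pass (adjusted p = 0.0964, and 0.0125 to 0.285 over its alternatives). PS-MP replicate 3 set most of that difference, with 317 CPM against 158 and 140 in the other PS-MP libraries. The transferrin receptor TFRC stood at 623 ± 31.9 and 552 ± 79.8 CPM (adjusted p = 0.414). Camera called the driver list higher (adjusted p = 0.0216), a call lost with an estimated correlation (adjusted p = 0.452), by fry (0.0647), without PS-MP replicate 1 (0.0511) and without PS-MP replicate 2 (0.0501), within a range from 0.000195 to 0.452. The count of drivers that were higher was 6 without PS-MP replicate 3, and 2 without control replicate 2, control replicate 3 or PS-MP replicate 1. HMOX1 lost its call without control replicate 2 or 3 or PS-MP replicate 1 or 2 (adjusted p from 0.0511 to 0.086). With replicate 3 of both groups left out, 11 drivers were higher and 1 lower, in a setting that called 4129 of 15503 genes.

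**Figure D2:**
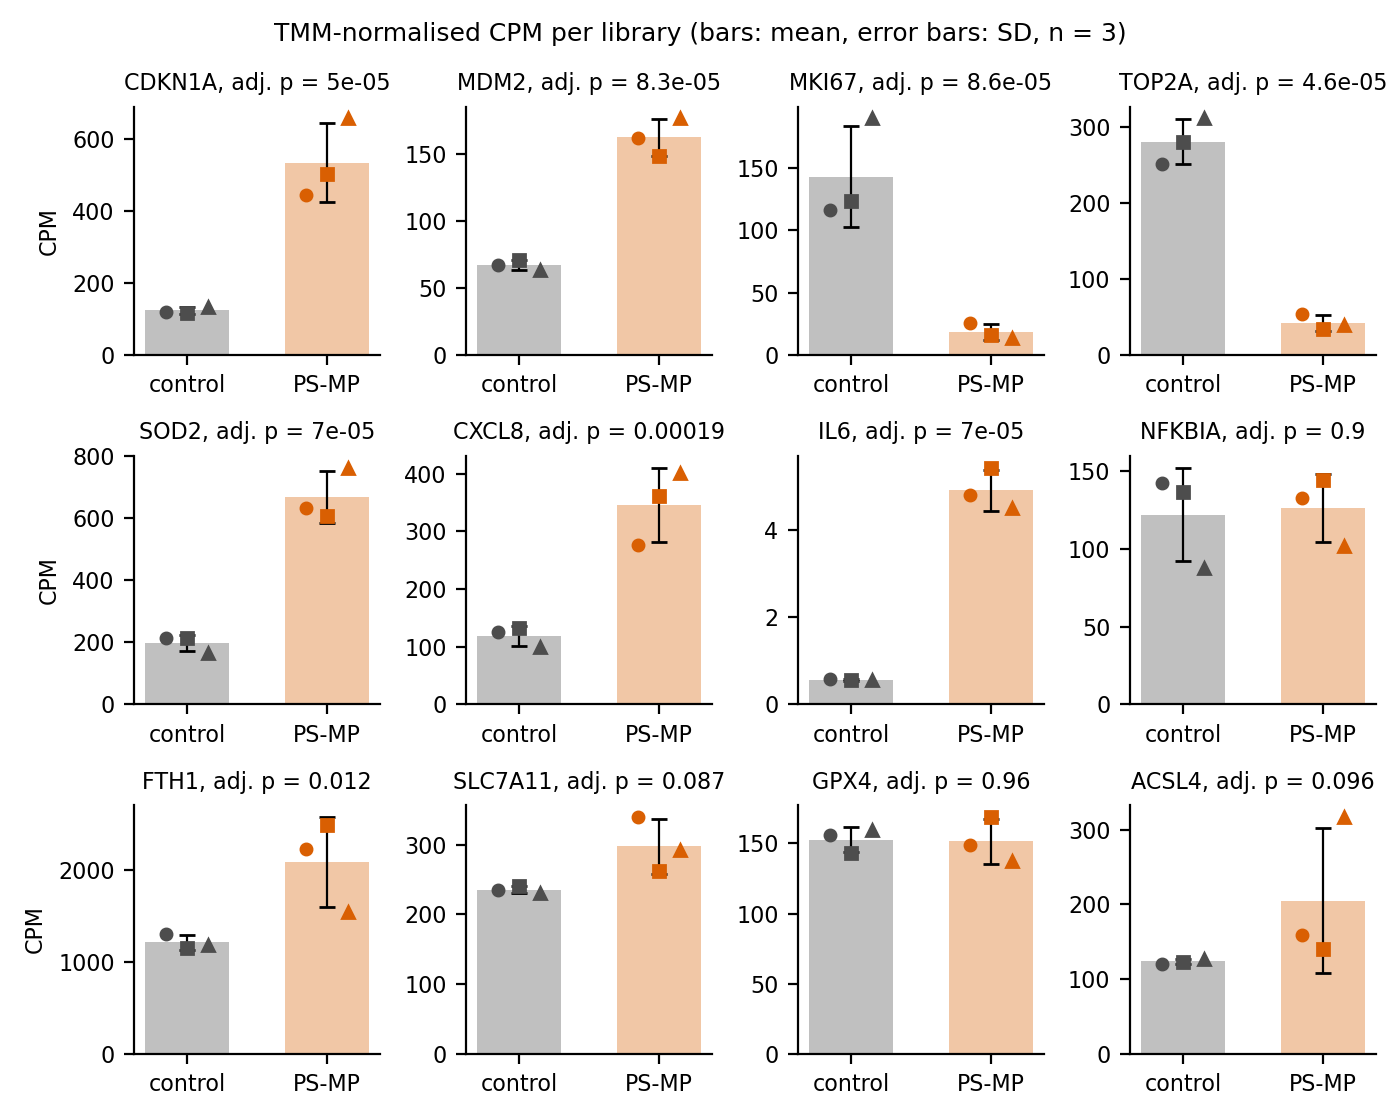
TMM-normalised CPM of 12 genes in the 6 libraries: circles, squares and triangles are replicates 1, 2 and 3 of the control (grey) and PS-MP (orange) groups, bars are means and error bars SD (n = 3), and each panel has its own axis from 0 and the edgeR adjusted p. CDKN1A, MDM2, SOD2, CXCL8 and IL6 are higher and MKI67 and TOP2A lower in every PS-MP library, the groups overlap for GPX4 and NFKBIA, and 1 library carries most of the ACSL4 difference.

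Medians of the stress-response lists ran from 0.12 for heat shock genes to 0.77 for metal-response genes, and no test compared the lists. The metal-response median, over 6 tested genes, was 0.55 without control replicate 2 and 0.91 without control replicate 3. NRF2 targets, whose baseline is known to be high in KEAP1-mutant A549 cells, held 2 genes that rose among 28 tested by both adjustments, FTH1 and HMOX1 (median 0.20). NQO1 (log2 fold change 0.08, adjusted p = 0.786) and TXNRD1 (0.03, adjusted p = 0.926) did not pass. FTH1 and HMOX1 lost their calls without control replicate 2 or 3 or PS-MP replicate 1 or 2 (adjusted p from 0.0501 to 0.086). DESeq2 called 5 NRF2 targets higher, and edgeR called 13 without both replicate 3 libraries. The NRF2 list call (camera adjusted p = 0.0151) was lost with an estimated correlation (adjusted p = 0.452), by fry (0.112) and without PS-MP replicate 1 (0.0544) or 2 (0.058), within a range that reached down to 9.29e-06. The ATF4 list, genes of the amino acid and integrated stress response, had 3 risers of 27 over all genes tested and 8 adjusted over the list alone (median 0.37), SESN2, NUPR1 (3.68-fold, adjusted p = 0.0148) and CEBPB, the last named after its value was seen. NUPR1 and CEBPB lost their calls without control replicate 1, PS-MP replicate 1 or PS-MP replicate 2 (adjusted p from 0.0647 to 0.153), CEBPB also without control replicate 2 (0.148) and NUPR1 also with no low-count filter (0.311). The number of ATF4 risers over all genes was 13 without PS-MP replicate 3 (median 0.57), 2 without control replicate 2, and 1 without control replicate 1, PS-MP replicate 1 or PS-MP replicate 2. Scores of the ATF4 list were 0.60 and 0.55 in PS-MP replicates 1 and 2 and −0.09 in PS-MP replicate 3. Its call (camera adjusted p = 0.00178) was lost with an estimated correlation (adjusted p = 0.51) and by fry (0.222), against a lowest value of 9.47e-15, and 19 members were higher without both replicate 3 libraries. Of 20 endoplasmic reticulum chaperone genes DNAJB9 rose by both adjustments (1.67-fold, adjusted p = 0.000952), and the list call (median 0.17, camera adjusted p = 0.0091) was lost with an estimated correlation (adjusted p = 0.27), the lowest value being 0.000646. Heat shock genes had 3 risers of 16 by both adjustments and 1 member lower within the list (median 0.12, camera adjusted p = 0.18, 0.0265 without control replicate 3, 0.0104 without both replicate 3 libraries and 0.0104 to 0.64 over its alternatives), and the risers were the collagen chaperone SERPINH1 (1.53-fold, adjusted p = 0.00346), HSPB1 and CRYAB. CRYAB, at 1.12 ± 0.0674 against 2.82 ± 1.13 CPM (n = 3, adjusted p = 0.025), lost its call without any 1 library other than PS-MP replicate 1 (adjusted p from 0.0559 to 0.0782). Metal-response genes had 3 risers and 1 fall among 6 tested, by both adjustments. They included the zinc exporter SLC30A1 (2.02-fold, adjusted p = 0.000211) and MT2A (1.93-fold, adjusted p = 0.00556), which shares sequence with other metallothioneins, while the zinc importer SLC39A10, named after its value was seen, fell (log2 fold change −0.99, adjusted p = 0.0107, and 0.0653 or 0.061 without PS-MP replicate 1 or 2). That list's call (median 0.77, camera adjusted p = 0.0166) was lost with an estimated correlation (adjusted p = 0.27) and without control replicate 1 (0.0627) or 2 (0.051), the lowest value being 0.00125. Without both replicate 3 libraries, 5 chaperone genes and 7 heat shock genes were higher and 1 heat shock gene lower, and the metal-response counts were 3 and 1.

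Of 28 tested lysosome and autophagy genes, 14 rose over all genes and 21 adjusted over the list alone, and no member fell (median 0.43). The 14 became 7 without PS-MP replicate 1, 8 without PS-MP replicate 2 and 9 without control replicate 1, with 10 to 14 without each of the other libraries. With the replicate number as a block they became 5. The protease CTSD rose 1.85-fold (96.9 ± 14.0 against 179 ± 18.5 CPM, n = 3, adjusted p = 0.00148) and the cholesterol carrier NPC2 1.62-fold (54.3 ± 5.35 against 88.1 ± 8.88 CPM, adjusted p = 0.00361). Camera called the list (adjusted p = 3.08e-10), a call lost with an estimated correlation (adjusted p = 0.0702), the highest of 17 alternatives that reached down to 3.55e-16. Leaving out replicate 3 of both groups, 21 members were higher. Particle uptake genes had 3 risers of 24 by both adjustments (median 0.15, camera adjusted p = 0.0687), FLOT2 (1.29-fold), SCARB1 (1.31-fold) and CTTN (log2 fold change 0.39, named after its value was seen). All 3 lost their calls without control replicate 1 or 2 or PS-MP replicate 1 or 2 (adjusted p from 0.0775 to 0.196), and also with total counts as the only scaling (0.0701 for FLOT2 and 0.0892 for SCARB1). The uptake list passed without control replicate 3 (0.0196), with no low-count filter (0.0129), with limma-voom (0.027), without both replicate 3 libraries (0.0111) and by fry (0.00774), within 0.00774 to 0.27 over its alternatives. Fatty acid synthesis genes had 3 risers of 18 over all genes and 4 within the list (median 0.16), FADS1, FADS2 (log2 fold change 0.60, named after its value was seen, and lost at 0.0963 to 0.166 without any 1 of the controls or PS-MP replicate 1 or 2) and ACSL1 (1.41-fold, adjusted p = 0.011, lost at 0.0513 without control replicate 1 and 0.0613 without PS-MP replicate 1). The 3 became 1 without control replicate 1 or PS-MP replicate 1 and 5 without PS-MP replicate 3. The list's call (camera adjusted p = 0.0166) was lost with an estimated correlation (adjusted p = 0.452), by fry (0.0535) and without control replicate 3 (0.0538) or PS-MP replicate 1 (0.0681), the lowest value being 0.000957. Cholesterol synthesis genes had 2 risers of 25 by both adjustments, among them MSMO1 (1.47-fold, adjusted p = 0.0395), whose call was lost without PS-MP replicate 1 or 2 or control replicate 1 or 3 (adjusted p from 0.0813 to 0.158) and with total counts as the only scaling (0.0576). This list was not called (median 0.14, camera adjusted p = 0.0941). Its scores were 0.28 and 0.34 in PS-MP replicates 1 and 2 and −0.17 in PS-MP replicate 3, and without the latter the adjusted p was 2.69e-06 and 8 members were higher, against an adjusted p of 1.45e-06 to 0.693 over its alternatives. With no low-count filter it was 0.0222. The 2 cholesterol risers became 0 without control replicate 1, control replicate 3 or PS-MP replicate 1, and 1 without control replicate 2. Once replicate 3 of both groups was left out, 9 uptake, 8 fatty acid and 15 cholesterol genes were higher, and 1 uptake and 1 cholesterol gene lower.

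Many interferon-stimulated genes were higher. Over all genes 12 of 23 tested members rose, and 8 or 9 did without any 1 library. Adjusted over the list alone, 17 rose and 1 fell (median 0.73). The antiviral GTPase MX1 rose 3.81-fold (1.16 ± 0.305 against 4.46 ± 0.368 CPM, n = 3, adjusted p = 0.000658) and IFIT2 2.57-fold (4.31 ± 1.28 against 11.1 ± 0.710 CPM, adjusted p = 0.0027). ISG15 also rose (log2 fold change 1.15), and OAS1 and USP18 did not pass (0.06 and −0.03). Camera called the list (adjusted p = 2.19e-09), a call lost with an estimated correlation (adjusted p = 0.0987), the highest of 17 alternatives that reached down to 1.58e-15. Excluding replicate 3 of both groups, 12 members were higher. Outside the lists, the largest rises among genes with a mean log2 CPM of at least 2 included the haem protein CYGB (6.66-fold, adjusted p = 0.000209), the pattern-recognition receptor CLEC4E (5.46-fold, adjusted p = 0.000107) and the interferon-inducible TRIM22 (5.15-fold, adjusted p = 0.000568). The cytokine IL32 (4.44-fold, adjusted p = 0.000107), PDZK1IP1 (4.10-fold, adjusted p = 0.00101) and the ammonium transporter RHCG (4.05-fold, adjusted p = 7.04e-05) were also among them. All of these were low in the controls, with means of 1.06 CPM (CYGB), 1.37 (CLEC4E), 3.02 (TRIM22), 2.15 (IL32), 3.11 (PDZK1IP1) and 3.97 (RHCG). LBP, the lipopolysaccharide-binding protein, was 4.32-fold higher on average (adjusted p = 0.0332), from 2.35 CPM in the controls. PS-MP replicate 3 held 21.2 CPM against 4.81 and 4.37 in the other PS-MP libraries, and the call was lost without any 1 of the controls (adjusted p from 0.121 to 0.192), with limma-voom (0.104) and with no low-count filter (0.401).

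Hypoxia genes had no member past the threshold by edgeR among 26 tested by either adjustment (7 at an unadjusted p under 0.05, and 1 lower by DESeq2), with a median of −0.18 and a camera adjusted p of 0.138, within 0.0197 to 0.832 over its alternatives, which was 0.0376 with no low-count filter, 0.0277 without control replicate 1 and 0.0197 without PS-MP replicate 2. Without PS-MP replicate 3, 1 member was higher. PS-MP replicate 3 scored −0.41 on this list and the other PS-MP libraries −0.08 and 0.03. Mesenchymal and TGF-beta genes had 2 risers of 25, and 5 adjusted over the list alone (median 0.17, and 0.05 without control replicate 3). Among them TGFBI rose 1.40-fold (589 ± 40.6 against 822 ± 136 CPM, n = 3, adjusted p = 0.0391), a call lost without any 1 of the 6 libraries (adjusted p from 0.054 to 0.15) and with total counts as the only scaling (0.0796). The list had 4 risers without PS-MP replicate 3 and 1 without any 1 of the controls or PS-MP replicate 1. The call of that list (camera adjusted p = 0.0361) was lost with an estimated correlation (adjusted p = 0.27), by fry (0.0535), without both replicate 3 libraries (0.0782) and without control replicate 2 (0.0615) or PS-MP replicate 3 (0.0824), the lowest value being 0.00414. No epithelial gene passed by edgeR among 16 tested by either adjustment (1 at an unadjusted p under 0.05, 0 by DESeq2), and the list's median of 0.04 and mean of −0.01 differed in sign (camera adjusted p = 0.921). Immediate early and MAPK feedback genes went both ways, with 4 risers and 3 falls among 22 tested and 5 and 3 within the list. These 4 and 3 became 1 and 2 without control replicate 1 or PS-MP replicate 1, 2 and 2 without control replicate 2, and 2 and 1 without PS-MP replicate 2. JUN rose 1.81-fold (adjusted p = 0.00227), ETV4 was 1.46-fold lower (adjusted p = 0.00634) and MYC was lower (log2 fold change −0.62, adjusted p = 0.0187, and 0.0891 or 0.0528 without PS-MP replicate 1 or 2). The median of that list was −0.02 and its mean 0.03, and camera gave the direction up with an adjusted p of 0.712. Fry for changes in either direction gave an adjusted p of 1.93e-06. With both replicate 3 libraries left out, the counts higher and lower were 4 and 2 for hypoxia, 6 and 1 for mesenchymal, 3 and 2 for epithelial and 9 and 5 for immediate early genes. Aryl hydrocarbon receptor targets had 1 riser of 7, ALDH3A1 (1.52-fold, adjusted p = 0.0116, and 0.0527 without control replicate 2, while 2 members rose without PS-MP replicate 3), and 3 adjusted over the list alone (median 0.25, camera adjusted p = 0.149, and 0.00936 by fry), while CYP1A1 (log2 fold change −0.75, adjusted p = 0.253) did not pass.

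Housekeeping lists and markers of other cell types completed the fixed set. Cytosolic ribosomal protein genes had a median of 0.19, with 1 riser, RPS19 (1.38-fold, adjusted p = 0.0345, lost at 0.0575 to 0.126 without control replicate 1, 2 or 3 or PS-MP replicate 1 or 2), and none adjusted over the list alone (7 at an unadjusted p under 0.05, 1 by DESeq2). Its list call (camera adjusted p = 0.00123) was lost with an estimated correlation (adjusted p = 0.577), by fry (0.149) and without PS-MP replicate 2 (0.0553), the lowest value being 2.61e-05. Nuclear-encoded oxidative phosphorylation genes had 2 risers and 1 fall of 30, and 3 and 1 within the list (median 0.08, camera adjusted p = 0.294), and 5 rose without PS-MP replicate 3. Without both replicate 3 libraries 10 rose and 1 fell, and the list passed (0.0213, within 0.0213 to 0.955 over its alternatives). Besides SDHC, named after its value was seen and lost at 0.0805 to 0.177 without any 1 of the controls or PS-MP replicate 1 or 2, COX6C, the other riser, was 1.37-fold higher (adjusted p = 0.0126, and 0.0554 to 0.072 without control replicate 1 or 2 or PS-MP replicate 1 or 2). NDUFV2 was 2.83-fold lower at 1.37 ± 0.171 against 0.480 ± 0.129 CPM (n = 3, adjusted p = 0.0193, and 0.0505 to 0.0865 without control replicate 2 or 3 or PS-MP replicate 1 or 2), which is uncertain because other annotated genes overlap its locus on both strands. None of the 13 mitochondrially encoded mRNAs passed by edgeR under either adjustment (1 at an unadjusted p under 0.05, 0 by DESeq2, median 0.03, camera adjusted p = 0.347, and 0.0298 without control replicate 1). Of the 6 tested alveolar type 2 markers 0 passed over all genes by edgeR, 1 rose adjusted over the list alone (2 at an unadjusted p under 0.05, 0 by DESeq2), and the median was 0.28 (camera adjusted p = 0.192). Without control replicate 3, 1 of them rose over all genes and the median was 0.02, against 0.37 without control replicate 2. Of 17 leukocyte markers 4 could be tested and 0 passed by edgeR under either adjustment (1 at an unadjusted p under 0.05, 0 by DESeq2). Their median was 0.49 (camera adjusted p = 0.0941, with 0.042 without PS-MP replicate 1, 0.049 without PS-MP replicate 2, 0.00508 with no low-count filter and 0.00508 to 0.481 over its alternatives), and S100A8, which epithelial cells also express, had a log2 fold change of 1.32 (adjusted p = 0.144). Of 14 fibroblast and endothelial markers 4 could be tested and DCN rose by both adjustments (2.28 ± 0.114 against 4.92 ± 1.78 CPM, n = 3, adjusted p = 0.0245, lost at 0.0518 to 0.0784 without any 1 of the controls or PS-MP replicate 1), with a list median of 0.36 (camera adjusted p = 0.138). That median was 0.06 over 5 tested markers without control replicate 3, and 0.44 without control replicate 1. Non-polyadenylated RNAs, listed as a possible sign of poly(A) selection or RNA quality, had 1 riser of 8, the histone gene H2BC4, whose family members share sequence (0.765 ± 0.328 against 1.94 ± 0.463 CPM, n = 3, adjusted p = 0.0418, lost at 0.0889 to 0.169 without control replicate 2 or 3 or PS-MP replicate 1 or 2), and 4 adjusted over the list alone (median 0.66). Most of the tested members are histone genes, and no test separated RNA quality from the change in cell-cycle genes. Camera gave that list an adjusted p of 0.0687, which was 0.0219 without control replicate 1, 0.0301 without control replicate 2 and 0.0132 without PS-MP replicate 3. It was also 0.0345 with total counts as the only scaling, 0.0158 with the replicate number as a block and 0.012 without both replicate 3 libraries, within 0.012 to 0.546 over its alternatives. The list scored 0.32, 0.34 and −0.55 in controls 1, 2 and 3 and 0.65, 0.96 and 0.14 in PS-MP replicates 1, 2 and 3. It was thus lowest in replicate 3 of both groups, and the groups overlapped. Without PS-MP replicate 3, 2 of its members rose.

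**Figure D3:**
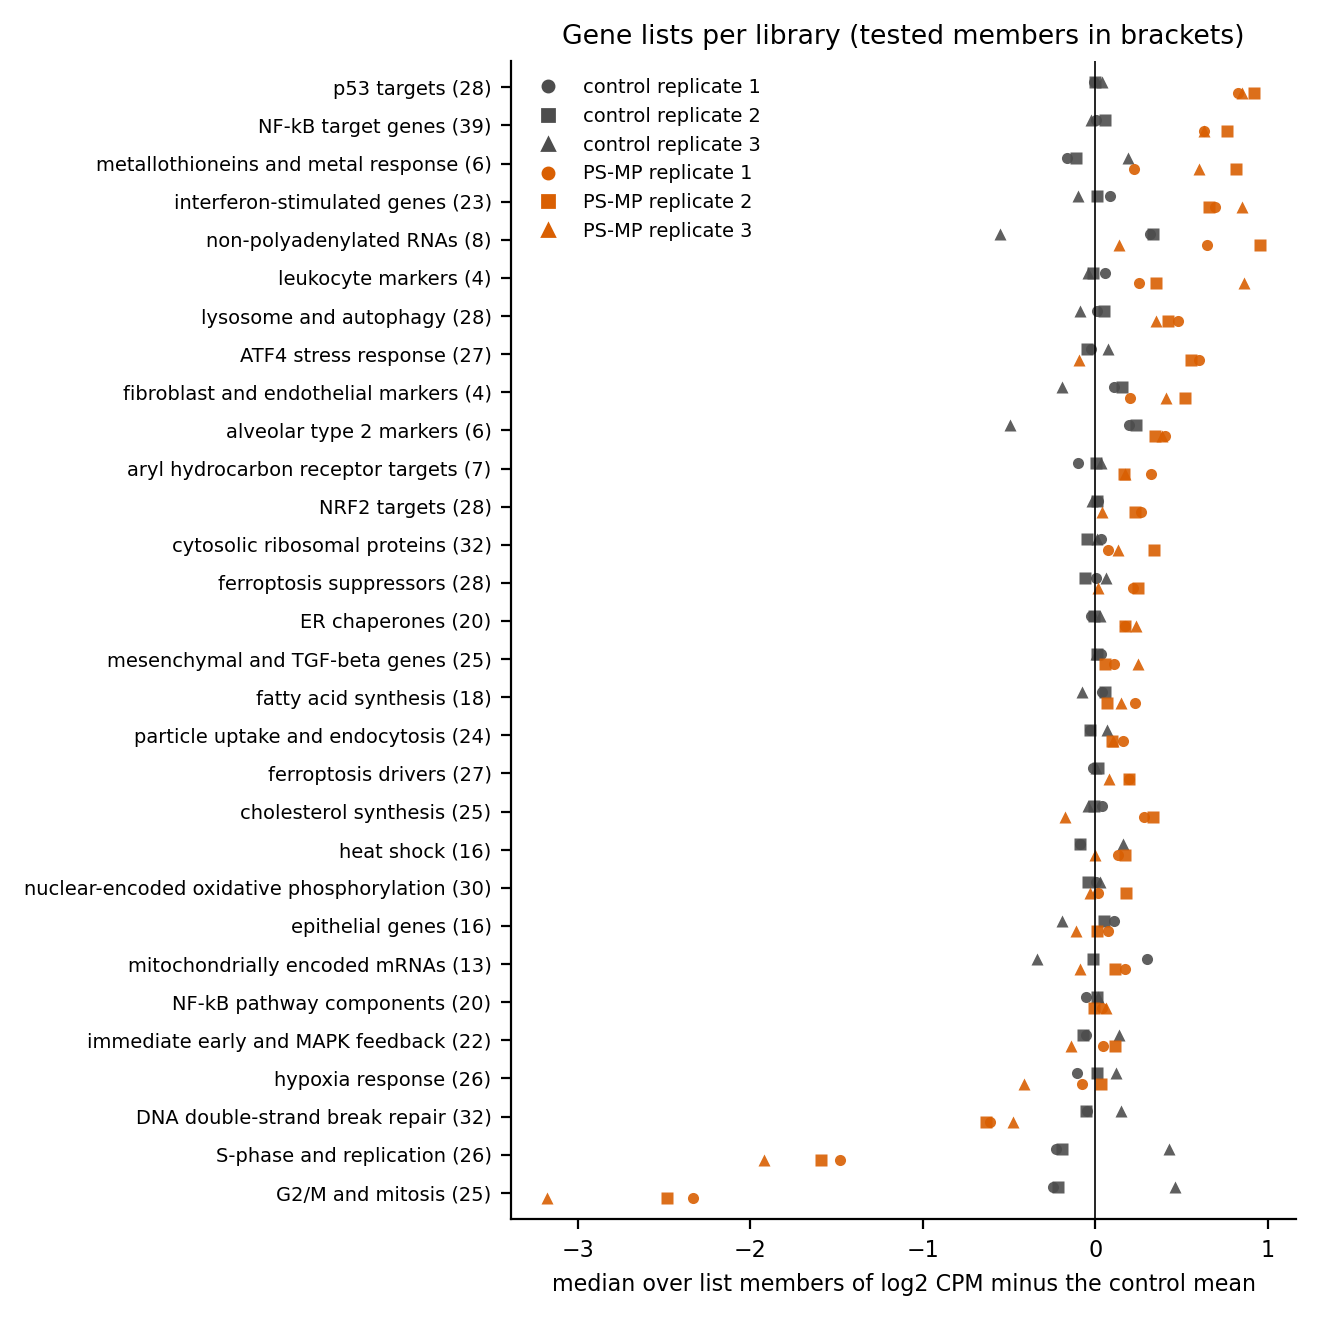
For each of the 30 gene lists, ordered by median log2 fold change, the x axis gives the median over tested members of log2 CPM minus the control mean, with 1 symbol per library (control grey, PS-MP orange; circles, squares and triangles are replicates 1, 2 and 3). The p53 and NF-kB target lists sit between 0.63 and 0.92 in all PS-MP libraries, the G2/M list between −3.18 and −2.33, and the triangles of replicate 3 lie farthest from 0 within each group on both cell-cycle lists.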

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

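The alternative that leaves out both replicate 3 libraries was chosen after seeing the data, and the others were planned. Of the 66 named genes, 42 kept their direction and their side of the threshold under every alternative. Over their 990 alternative values, 878 did so, 102 no longer passed, 2 newly passed and 8 changed direction. Of the 30 lists, 6 kept both throughout and 5 changed direction somewhere. All 1478 called genes kept their sign under DESeq2, which called 1658 genes, 1430 of them shared.

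The number of changed genes was 558 when a log2 fold change of at least 1 was also required, which follows from the stricter rule, and ran from 771 to 1696 with 1 library left out (771 without PS-MP replicate 1, 1696 without PS-MP replicate 3). It was 4129 of 15503 tested genes with both replicate 3 libraries left out. With the replicate number as a block (replicate block) it was 750, 333 higher and 417 lower. Calls lost under the block included those of LBP, H2BC4, CRYAB, DCN, ALDH3A1, IRAK1, AIFM2 and ACSL1. Also lost were TGFBI, RPS19, COX6C, MYD88, SCARB1, FLOT2 and NDUFV2, with adjusted p from 0.0505 to 0.119 across all of these genes. Deviations of libraries with the same number correlated at −0.0947, −0.108 and −0.181, so they did not rise and fall together over all genes. These values cannot show whether libraries with the same number were handled together.

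The number of lists called was 15, and 3 with an estimated correlation, which allows for genes that vary together. Ferroptosis suppressors passed with no low-count filter (adjusted p = 0.039), limma-voom (0.0297) and both replicate 3 libraries left out (0.000179), and ranged from 0.00151 to 0.245 with 1 library left out. Ferroptosis drivers did not pass with an estimated correlation (0.452) or fry (0.0647), with 0.000195 to 0.0511 when 1 library was left out. Beyond these settings' own construction, the cause was not tested.

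Directions reversed for 5 lists and 2 named genes. With both replicate 3 libraries left out these were hypoxia (adjusted p = 0.536), epithelial genes (0.966), NFKBIA (log2 fold change −0.014) and GPX4 (0.084). Epithelial genes also reversed under the block (0.972), and NFKBIA with total counts as the only scaling (−0.016). With 1 library left out, some reversed within these ranges: epithelial genes 0.685 to 0.955, immediate early genes 0.282 to 0.957, oxidative phosphorylation 0.0531 to 0.955, mitochondrially encoded mRNAs 0.0298 to 0.688, NFKBIA −0.15 to 0.18 and GPX4 −0.10 to 0.056. For these reversals the cause was not tested.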

Other observations

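The tests of the replicate 3 libraries alone, of leukocytes, of exchanged labels and of growth state were chosen only after the results were seen, and the others were planned.

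The fall of the S-phase and G2/M genes had a median of −2.17 over 51 genes. Gene length and GC content are argued against, since the median stayed at −2.17 (upper quartile −1.57) after the trend on both had been removed. The choice of scaling made little difference, with −2.16 as the highest and −2.24 as the lowest median under 4 scalings, the main one included. TMM factors lay between 0.9593 and 1.041, so these scalings could hardly have differed. All 4 rest on the libraries' own counts and could not show a change in total RNA per cell. The replicate 3 libraries cannot be the only source, since the median was −1.7 in the 2 libraries against 2 without them. A lower proliferation of the exposed cells may account for the pattern, as a hypothesis that was not itself tested. Because many repair genes follow the cell cycle, the lower repair list may share that source, which was not tested.

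The rise of the NF-kB target list is argued not to come from leukocytes. The summed CPM of PTPRC, TYROBP, LYZ, FCER1G, CD3E and CD3D, with 2 to 7 counts per library, came to 0.013% of the list's rise of 1735 CPM. Under the same 4 scalings, which could hardly have differed, the lowest median of the NF-kB target list was 0.714. After removal of the length and GC trend that median was 0.708 (lower quartile 0.272). A response of the exposed cells may explain it, as a hypothesis. Whether the polystyrene itself or something carried with the particles, such as endotoxin or another additive, set it off was not tested.

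Replicate 3 of each group stood apart from replicates 1 and 2. An exchange of labels between the groups is argued against, since each replicate 3 library correlated more with its own group than with the other, by at least 0.0075. A difference in growth state between cultures may contribute: the cell-cycle genes deviated by 0.663 in control replicate 3 and by −0.728 in PS-MP replicate 3, where 10000 random lists of 51 genes matched on expression gave −0.0666 to 0.122 and −0.132 to 0.0677. The random lists were not matched on how far genes vary together. The comparison therefore shows that the cell-cycle genes deviated, and not why. The NF-kB targets deviated by −0.0405 and −0.144, the p53 targets by 0.0577 and 0.0526, the interferon-stimulated genes by −0.151 and 0.179 and the lysosomal genes by −0.13 and −0.0412. Like the cell-cycle genes, the interferon-stimulated genes thus moved in opposite directions in the 2 libraries, by a smaller amount. The labels give no batch, and a batch effect was not tested.

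Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called as many genes. The other 9 called 0 by edgeR, with 112 to 1536 genes at an unadjusted p under 0.05 and 0 to 49 by DESeq2, against 3705 and 1658 in the real split. So few splits cannot give a share under 0.05. Each of the other 9 also mixed control and PS-MP libraries in both groups, which widens the spread within groups and lowers the calls. Their counts are therefore no baseline for chance.

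A senescence-associated secretory profile was tested with 25 secretory factors outside the NF-kB list. Secreted factors on the NF-kB list, such as IL6 and CXCL8, which rose, were left out, so the result covers only the remaining factors. The 18 tested of the 25 factors had a median of 0.234, with 2 higher (TIMP1 and TIMP2) and none lower. The median lay below the 0.3 set beforehand and camera gave p = 0.0506 (0.319 with an estimated correlation), so such a profile may or may not be present and cannot be told apart from no change with these members.

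Among 248 families of genes with a shared symbol root and at least 8 members outside the lists, camera called 13, 5 higher and 8 lower, each with an adjusted p of 0.957 with an estimated correlation. Kinesins (KIF) had 11 of 33 members lower and 2 higher (median −0.269), nucleoporins (NUP) 12 of 24 lower (−0.483) and centrosomal proteins (CEP) 11 of 39 lower and 1 higher (−0.347). Collagens (COL) had 4 of 21 higher (0.475), annexins (ANXA) 5 of 17 (0.176), clustered protocadherins (PCDHB) 3 of 9 (0.621) and UDP-glucuronosyltransferases (UGT) 2 of 11 (0.845), the last pair of families with members that share sequence. Total-count scaling moved the median of all genes by −0.0658, less than each of these medians.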
